A study of Homo sapiens with 22 samples.

How the data were processed

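ATAC-seq peak lists of 22 libraries from human primary naive CD4 T cells were used. Per the labels' protocols, cells were purified from blood mononuclear cells, DNA was cut with the Nextera transposome and amplified, and DNA of 200 to 400 bp was kept. The submitters' processing notes name STAR 2.4.0c, Bowtie 1.0.0, MACS2 2.1.0.20140616 and the genome build hg19, without saying which step each served. Read trimming, the shift of reads for the transposase, the handling of duplicates and the calling threshold are not given in the sources used here.

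Each deposited file lists the peaks of 1 library, so the authors called peaks per sample and did not pool replicates. Per the file headers, each summit carries a pileup, which is a signal of stacked tags that the authors did not scale for depth. Per the file headers, each summit also has a fold enrichment, a ratio of the pileup to background. In the deposited values this ratio equals the pileup plus 1 over a constant background plus 1 in every library. The authors also deposited −log10 p and −log10 q for each summit. Fold and q are the authors' values per peak and were used to rank, bin or filter peaks and to work out the background and the enrichment of each library. The authors' gene and region class (promoter, upstream, exon, intron or intergenic) were used as deposited. The class borders are not given in the sources used here.

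Summits of the same interval were joined into 1 peak. Mitochondrial and Y intervals and the genes XIST and TSIX were left out. Peaks of all libraries were merged where they shared at least 1 bp, which gave 139767 regions with a median length of 221 bp, and a region was present in a library that had a peak in it. A region's gene and class were the most frequent among its peaks. Of all peaks, 8.68% named several genes. Of 19380 gene symbols in the lists, 95.6% matched a current or older symbol in a gene table of GRCh38.p14, which was used for names only. Coordinates are in hg19, as in the files.

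Groups came from the sample titles. For 1 library of the CD3-only 60 h group, the title and source name give 60 h while the activation label gives 24 h, and the library was kept at 60 h. The labels do not say whether replicates came from separate donors or cultures, so p-values measure the spread between these samples, which may be technical. The same replicate numbers stand in several groups, and no label says that a number marks a shared donor or day.

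Opened regions had a peak in every library of the costimulated group at a time and in no naive library, closed regions the reverse, and common regions a peak in all. CD28-dependent regions were opened at 5 h and had a peak in neither CD3-only library of 5 h. A-FOS-sensitive regions were opened at 5 h, had a peak in both GFP libraries and in neither A-FOS library. Peak numbers, class shares and recovery of regions were compared with exact two-sided permutation tests, within time points for CD28, and the class shares were adjusted by Benjamini-Hochberg over 5 classes. Each region found in at least 3 of the 11 naive and costimulated libraries was tested by a two-sided Fisher exact test with Benjamini-Hochberg adjustment. Shares have exact 95% binomial intervals (Clopper-Pearson), which cover counting error only. Odds ratios are across regions, and the score bins are 10 bins of the authors' −log10 q in costimulated or GFP libraries. A threshold of 0.05 was used throughout.

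There were 15 gene lists: cytokines, activation receptors, the AP-1 family, NFAT, NF-kB and EGR factors, growth and metabolism, cell cycle, naive and quiescence genes, TCR signalling, T helper lineage, anergy regulators, markers of B cells, monocytes, NK and CD8 cells, and erythroid cells and platelets, and constitutive control genes. They held 267 different genes. The number of list members with an opened region was set against 10000 random gene sets matched on the number of merged regions per gene, two-sided. CD28 dependence and A-FOS sensitivity of a list's opened regions were tested by Fisher's exact test against all other opened regions. Adjustment was over the 15 lists. The design, the lists, the named-gene rule and the other settings listed below were fixed before the data were examined. The tests of regions per gene and of the share of a library's regions at a list's genes, and the limit on enrichment over background, were added afterwards.

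Genes were named by a fixed rule. For each of the opened, closed, CD28-dependent and A-FOS-sensitive sets at 5 h these were the 8 genes with most such regions and up to 4 members of each list with most such regions. Up to 2 list members with a common region and no opened or closed one were named as not changed, and 12 genes were named whatever their value. The printed region of a gene was the one with the highest median fold enrichment by the authors. Genes that passed a test adjusted over the list alone were named as well, as were genes of the exon regions in the closing section, which were chosen after their values were seen.

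Depth was not given as read totals. The background behind the fold enrichment, divided by the shortest peak length as a stand-in for the fragment length, gave a relative tag number of 0.765 to 5.66 times that of naive replicate 2. The smallest enrichment that was called lay between 5.55 and 16.7 times the background, at lower values in libraries with more tags, so that shallow lists missed weak regions. Alternatives were a −log10 q of at least 10, covered length in place of peak number, peaks covering at least 50% of a region, lists of equal length, promoter and upstream regions only for the gene lists, a replicate block, leaving out each library in turn, and an enrichment of at least 20 times the background.

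The scripts were tested on simulated data. In simulated regions with no effect the Fisher test of activated against naive libraries called 0 of 32029, with 200 planted regions it called 0 of 31997 although 100% of the planted ones were at unadjusted p under 0.05, and with 8000 planted it called 8021, including all 8000. The exact test of peak number passed in 3.5% of 200 simulations with no effect and in 91% with a planted log2 difference of 1.2. The test of gene lists at 5 h called 20 of 20 planted lists and 1 of 280 others, and the stratified odds ratio gave 2.01 for a planted 2. Nearly all genes of a planted list were given a region of the class, so power for weaker list differences was not measured. The test of regions per gene, on 3000 simulated genes with 200 changed 4-fold, put 99% of these at unadjusted p under 0.05 and called 0 after adjustment. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 was used. The planned search for AP-1 motifs was not run, since it needs the hg19 sequence, which was not used here.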

Results

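Open chromatin was mapped by ATAC-seq, in which a transposase puts sequencing adapters into accessible DNA, in 22 libraries of naive CD4 T cells taken from human peripheral blood. 3 libraries came from unstimulated naive cells. Cells stimulated with beads that carried antibodies to CD3, part of the T cell receptor complex, and to CD28, a costimulatory receptor, gave 3 libraries at 5 h, 3 at 24 h and 2 at 60 h. Cells given anti-CD3 without anti-CD28 gave 2 libraries at each of these times. In a further set, cells were electroporated before 5 h of costimulation with GFP protein as a control, in 2 libraries, or with A-FOS, in 2 libraries. A-FOS is a dominant-negative protein that binds JUN proteins and keeps the AP-1 transcription factor off DNA. A single library held naive cells electroporated without protein and not activated. The series asks how activation, CD28 and AP-1 activity shape the opening of chromatin.

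The lists held between 13435 and 55376 peaks per library, with a median of 32064, and covered 5.32 to 24.7 Mb. The total number of reads is not known from the lists. Relative tag numbers, worked out from the background behind the authors' fold enrichment, ran from 0.765 to 5.66 times that of naive replicate 2. Across all libraries, 686815 peak calls merged into 139767 regions, of which 5985 had a peak in all 22 libraries and 80737 in a single library. The median overlap of 2 libraries, as shared over total regions, was 47.8% within a group and 38.9% between groups. No 2 libraries shared more than 0.0357% of identical intervals, so none was counted as a copy.

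The genes with most regions opened by 5 h of activation were INPP4B, CAMK2D, PDE4B, ETS1, FHIT and NRP1. A region was counted as opened when it had a peak in all 3 libraries at 5 h and in none of the 3 naive libraries, and 5363 regions met this. The ranking by gene, here and below, was not scaled for the number of merged regions per gene. Genes with many regions could therefore rank higher. INPP4B, a phosphoinositide phosphatase, had the most, with 15 opened regions, and its number of regions per library was 3.0 ± 1.0 in naive cells and 32.7 ± 16.8 at 5 h (SD, n = 3 each). CAMK2D, a calcium and calmodulin-dependent kinase, PDE4B, a phosphodiesterase of cyclic AMP, ETS1, a transcription factor, FHIT and NRP1, a coreceptor, had 12 opened regions each. PDE4B had 4.0 ± 1.7 regions per library in naive cells and 26.0 ± 3.6 at 5 h, and ETS1 had 8.67 ± 2.89 and 34.0 ± 4.4. Genes named for opened regions were chosen in these same libraries, so their higher counts at 5 h follow in part from the choice. RBMS1 had 11 opened regions, and BACH2, a repressor that restrains effector differentiation, had 10, as did KLF12, NEK7 and TIAM1, an activator of Rac. In the other direction, 4 regions had a peak in all 3 naive libraries and in none of the 3 at 5 h: 3 lay in introns of SERINC2, DAB1 and RIN3, and 1 lay upstream of SNX9. The naive lists were shorter, and with lists of equal length 315 regions counted as closed and 1025 as opened.

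The number of peaks rose with costimulation. Naive libraries had 17596 ± 7119 peaks (SD, n = 3), and the 8 costimulated libraries had 39892 ± 10213. The ratio of geometric means was 2.30-fold, a log2 difference of 1.2 (exact two-sided permutation test, p = 0.0121). By time, the number was 43909 ± 10861 at 5 h (n = 3), 32716 ± 10070 at 24 h (n = 3) and 44631 ± 6605 at 60 h (n = 2). These were 2.57, 1.88 and 2.65 times the naive number, and the smallest p that these single-time tests can reach is 0.1. With peaks limited to a −log10 q of at least 10 the test gave p = 0.0970, and with peaks of at least 20 times the background p = 0.127, both by exact permutation. Naive replicate 1, with 25816 peaks, stood above naive replicates 2 and 3, with 13538 and 13435. Without it 8325 regions counted as opened at 5 h, a count that leaving out a library can only keep or raise. That count was 2219 with the q limit and 774 with the enrichment limit.

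**Figure D1:**
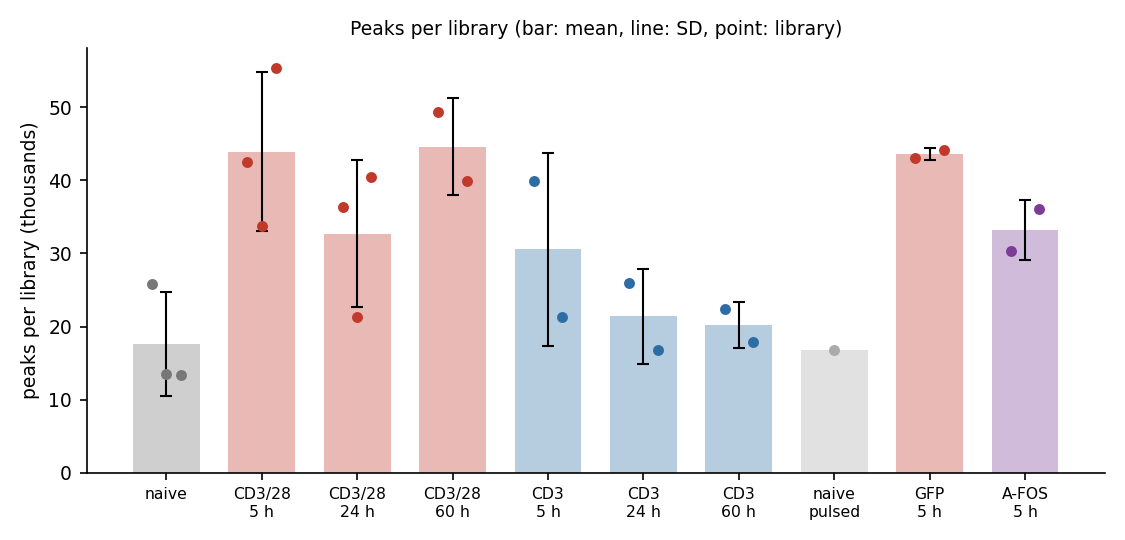
The number of peaks per library is plotted for each of the 10 groups, with points for libraries, bars for group means and lines for the SD. The 3 naive libraries lie between 13435 and 25816, and the 3 libraries costimulated for 5 h lie between 33778 and 55376.

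Among the gene lists fixed before the data were examined, TCR signalling genes had the highest share of members with an opened region at 5 h, 15 of 20 measured, against a mean of 9.06 in random gene sets matched on the number of regions per gene (two-sided permutation of genes, p = 0.00720, adjusted p = 0.108 over 15 lists). PTPRC, the CD45 phosphatase, had 8 opened regions, CD247, the CD3 zeta chain, had 6, and CD28 itself had 3. PTPRC had 4.0 ± 1.0 regions per library in naive cells and 28 ± 12 at 5 h (SD, n = 3 each). Naive and quiescence genes had opened regions at 14 of 22 members, against 9.84 in matched sets (permutation, adjusted p = 0.373): FOXP1, which supports quiescence, had 8, and TCF7, a transcription factor of naive cells, had 4. Activation receptors had them at 12 of 22 members, against 8.13 (permutation, adjusted p = 0.373), among them CTLA4, an inhibitory receptor, with 6, and IL2RA, the high-affinity IL-2 receptor chain, with 4. Anergy regulators had them at 9 of 16 members, against 5.51 (permutation, adjusted p = 0.373), led by CBLB, a ubiquitin ligase that dampens activation, with 9, and IKZF1 with 6. T helper lineage genes had them at 11 of 20 members, against 8.99 (permutation, adjusted p = 0.991), led by RUNX1 with 7 and AHR and RORA with 5 each. Cytokine genes had them at 8 of 21 members, against 6.57 (permutation, adjusted p = 1): IL21 had 4, IFNG and TNFSF11 had 3 each, and IL2 had 1. No list passed the test at 5 h. TCR signalling genes passed without naive replicate 1 or 3 (permutation, adjusted p = 0.021 and 0.033), and activation receptors and anergy regulators without costimulated 5 h replicate 3 (0.027 and 0.0375).

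The transcription factor families that act early in activation did not pass the test against matched genes at 5 h. NFAT, NF-kB and EGR genes had an opened region at 9 of 20 members, against 7.09 in matched sets (permutation, adjusted p = 0.991), with 7 at NFATC2 and 3 at NFATC1. AP-1 family genes had one at 6 of 15 members, against 5.00 (permutation, adjusted p = 1). ATF3 and BACH1 had 2 each and BATF, a partner of JUN in T cells, had 1, while FOS, FOSB and JUN had none. JUN had 1 region in every library, and FOS had 3.33 ± 1.53 regions per library in naive cells and 4.67 ± 0.58 at 5 h (SD, n = 3 each). Growth and metabolism genes had opened regions at 6 of 20 members, against 8.09 (permutation, adjusted p = 0.991), with 2 at MYC, a driver of T cell growth. Cell cycle genes had them at 4 of 21, against 4.17 (permutation, adjusted p = 1), with 6 at CCND2. CD69, an early activation marker, and CCR7, a homing receptor, had 1 opened region each. The opened regions of CD69, CCR7 and BATF had a peak in 0 of 2 GFP, 0 of 3 costimulated 24 h and 0 of 2 costimulated 60 h libraries. The CCR7 region had a peak in the electroporated naive library. Genes with a common region and no opened or closed one at 5 h included TFRC, SLC2A1, SLC2A3, CDK4, CCNE1, KLF2, TXNIP, LCP2, VAV1, GATA3, STAT3 and TGFB1.

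Marker genes of other blood cells did not pass the test against matched genes at 5 h. B cell markers had an opened region at 3 of 10 measured members, against 3.26 in matched sets, and monocyte markers at 2 of 11, against 1.08. NK and CD8 markers had one at 3 of 12, against 2.32, and erythroid and platelet markers at 0 of 5, against 0.21. The constitutive control genes had one at 3 of 16, against 3.09 (permutation, adjusted p = 1 for each of these lists). EBF1, a B cell transcription factor, had 3, KLRF1, an NK cell receptor, had 2, and CLEC7A, a myeloid receptor, had 1. The share of a library's regions that lay at these 4 marker lists did not pass a test between activated and naive libraries (exact permutation test, smallest adjusted p = 0.758).

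Regions per gene were also compared gene by gene between the 8 costimulated and the 3 naive libraries, a test added after the data had been examined. No gene passed an exact two-sided permutation test with Benjamini-Hochberg adjustment over all 16541 genes tested, with a smallest adjusted p of 0.152, and 2264 genes were at unadjusted p under 0.05. The smallest p this design allows is 0.00606. Regions per gene were not scaled for the 2.30-fold larger number of peaks. Adjusted over the list alone, 5 of 20 TCR signalling genes rose, among them PTPRC, FYN, CD5 and CD4, by 16.6, 16.4, 10.5 and 2.75 regions per library. Adjusted over the list alone, 6 of 16 anergy regulators rose, namely IKZF1 by 14.0, CBLB by 12.8, CTLA4 by 9.42, NT5E by 5.04, RNF128 by 1.25 and EGR2 by 1.12 regions. In the same way 4 of 20 NFAT, NF-kB and EGR genes rose, led by NFKB1 by 11 and NFATC2 by 8.79 regions. Of the activation receptors 3 of 22 rose, IL12RB2 by 6.29, SLAMF1 by 4.71 and CD274 by 2.62 regions, and of the T helper genes 3 of 20, STAT4 by 12.5, AHR by 11.3 and IKZF2 by 7.79 regions, both adjusted over the list alone. The other lists had 0 such genes.

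Opened regions lay mostly in introns and between genes. Of the 5363 regions opened at 5 h, 45.4% were intronic (95% exact interval 44.1 to 46.8), 28% intergenic and 9.53% in promoters (8.76 to 10.3) by the authors' annotation. Of the 8723 regions common to all 6 naive and 5 h libraries, 79.7% were in promoters (78.8 to 80.5). RBMS1 had an opened intronic region on chromosome 2 from 161274096 to 161274888 (hg19), and NRP1 had an opened intergenic one on chromosome 10 from 33425252 to 33426348, with median fold enrichments by the authors of 18.3 and 17.3 at 5 h. IL2RA had an opened region upstream on chromosome 10 from 6112607 to 6113066, and CTLA4 had one upstream on chromosome 2 from 204725701 to 204726587. Over whole libraries, the promoter share of peaks fell from 62.5% ± 10.6 in naive cells to 36.4% ± 6.5 in the 8 costimulated libraries (SD, n = 3 and n = 8, exact permutation test, adjusted p = 0.0152 over 5 classes). The intron share rose from 13.6% ± 4.9 to 27.1% ± 2.5 (exact permutation, adjusted p = 0.0152). The intergenic share was 14.0% ± 3.4 and 24.5% ± 6.5 (exact permutation, adjusted p = 0.0707), and neither the upstream share (adjusted p = 0.174) nor the exon share (adjusted p = 0.430) passed. The promoter and intron differences did not pass when naive replicate 2 or naive replicate 3 was left out, with adjusted p = 0.0556 in each case by the exact permutation test. With 2 naive libraries that test has fewer arrangements and a higher smallest p, so a missed threshold is not by itself a lost difference. Without naive replicate 3 the differences were still −22.25 points for promoters and 11.5 for introns. The upstream difference passed without naive replicate 1, at 2.64 points, and the intergenic one without costimulated replicate 3 of 5 h or of 24 h, at 8.80 and 9.25 points. With lists of equal length the differences were smaller for promoters, at −15.0 against −26.1 points, and for introns, at 9.22 against 13.5, and those of 0.54 upstream and 5.22 between genes passed (exact permutation, adjusted p = 0.0152 each).

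**Figure D2:**
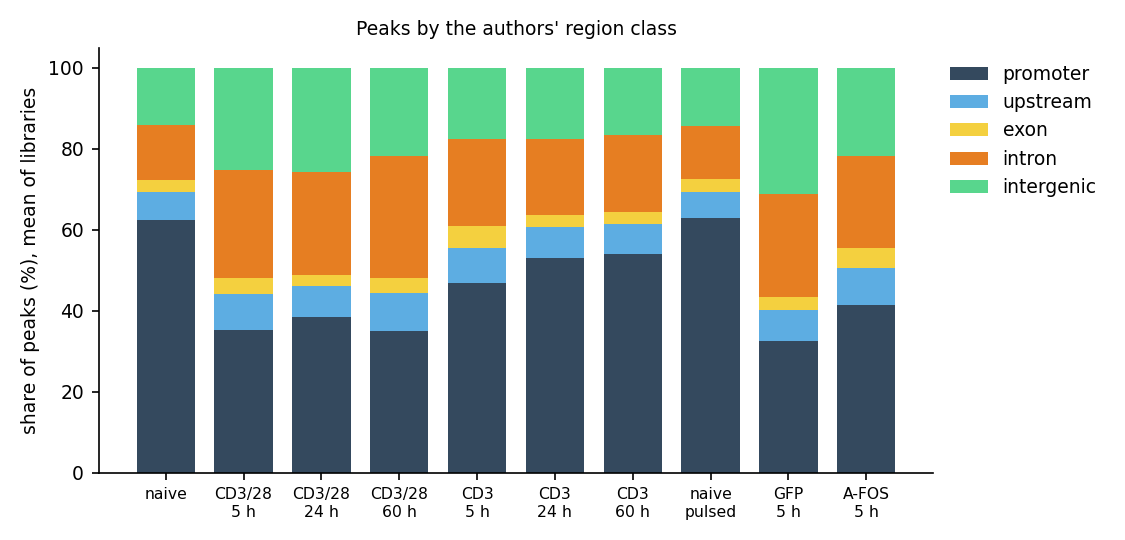
The mean share of peaks in each of the authors' 5 region classes, in percent, is stacked for each group of libraries. The promoter part is 62.5% in naive libraries and 32.5% in the GFP libraries costimulated for 5 h.

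Regions opened at 5 h were found to different degrees at later times. CAMK2D and PDE4B had 7 and 6 regions opened at 24 h and 12 and 17 at 60 h, while IL21, a cytokine of follicular help, had 8 and 12. ETS1 had 4 at 24 h and 27 at 60 h, FOXP1 had 10 and 26, and BACH2 had 10 and 14. These counts are not comparable between times, since a region had to be in 3 of 3 libraries at 24 h and in 2 of 2 at 60 h. In all, 4074 regions were opened at 24 h and 11573 at 60 h. Of the 5363 regions opened at 5 h, 1510 (28.2%) had a peak in every costimulated library of 24 and 60 h, and 603 (11.2%) had one in none of them. Of those opened at 60 h, 2665 (23%) had a peak in no costimulated library of 5 or 24 h. The regions closed against naive numbered 168 at 24 h and 159 at 60 h, with 43 in both sets, and with lists of equal length 1214 and 1208. A region in an intron of CD28, on chromosome 2 from 204584606 to 204585399, was closed at both times, as were the regions at SERINC2, RIN3 and SNX9 closed at 5 h, while CCR7 had an intergenic region closed at 60 h. The CD28 region had a peak in 1 of 3 costimulated 5 h, 2 of 2 GFP and 2 of 2 A-FOS libraries. It had no peak in the electroporated naive library, so its closing did not separate all activated from all naive libraries. Promoters held 41.7% of the regions closed at 24 h (95% exact interval 34.1 to 49.5), and intergenic sequence held 59.1% of those closed at 60 h (51.1 to 66.8).

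The counts by time gave no list of genes past the test. Leaving out a library can only keep or raise a count of opened regions, since fewer libraries then have to meet the condition. Without replicate 2 of the 24 h group 8413 regions counted as opened at 24 h, and without replicate 1 or replicate 2 of the 60 h group 17491 or 26836 counted as opened at 60 h. Counts at 24 h were 1017 with the q limit, 1500 with peaks covering at least 50% of a region, 1636 with the enrichment limit and 1830 with lists of equal length, and at 60 h 2996 with the q limit and 2386 with equal lists. At 60 h, T helper lineage genes had an opened region at 17 of 20 members against 12.6 in matched sets, and TCR signalling genes at 18 of 20 against 13.3 (permutation, adjusted p = 0.154 for each). Monocyte markers had one at 6 of 11 measured members at 60 h against 2.48 (permutation, adjusted p = 0.154), and AP-1 family genes at 4 of 15 against 8.21 (adjusted p = 0.154). At 24 h NFAT, NF-kB and EGR genes had one at 10 of 20 members against 6.30, and no list passed (permutation, adjusted p = 1 for every list). Among closed regions, naive and quiescence genes came nearest, with 3 of 22 members at 60 h against 0.677 (permutation, adjusted p = 0.843). A Fisher exact test of each of 35618 regions between 8 costimulated and 3 naive libraries called 0 regions, with a smallest adjusted p of 0.143, and 2947 regions were at unadjusted p under 0.05. The smallest unadjusted p these libraries allow is 0.00606, so a change at few regions could not pass.

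Without CD28 a part of the regions opened at 5 h was missing, and its size depended on how peaks were limited. Of the 5363 regions, 1796 (33.5%) had a peak in neither CD3-only library of 5 h, 1552 (28.9%) had one in both and 2015 (37.6%) in 1 of them. With lists of equal length 176 of 1025 had a peak in neither and 406 in both, and with peaks of at least 20 times the background 44 of 774 in neither and 271 in both. INPP4B had 11 of these CD28-dependent regions, CAMK2D, KLF12 and PDE4B had 7 each, and ACVR1C, RBMS1 and TIAM1 had 6 each. INPP4B had 6.0 ± 1.4 regions per library with anti-CD3 alone at 5 h (SD, n = 2), where costimulated cells had 32.7 ± 16.8 (n = 3). APBB1IP, an adaptor that links receptor signals to integrins, had 5 of them and 6.0 ± 1.4 against 15.7 ± 3.8 regions per library. Both genes were named for regions absent from these CD3-only libraries, so the lower counts of INPP4B and APBB1IP follow in part from that choice. In the reverse direction, 39 regions had a peak in both CD3-only libraries and in no costimulated library of 5 h. Of the CD28-dependent regions, 1087 (60.5%) had a peak in no CD3-only library of 24 or 60 h either.

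**Figure D3:**
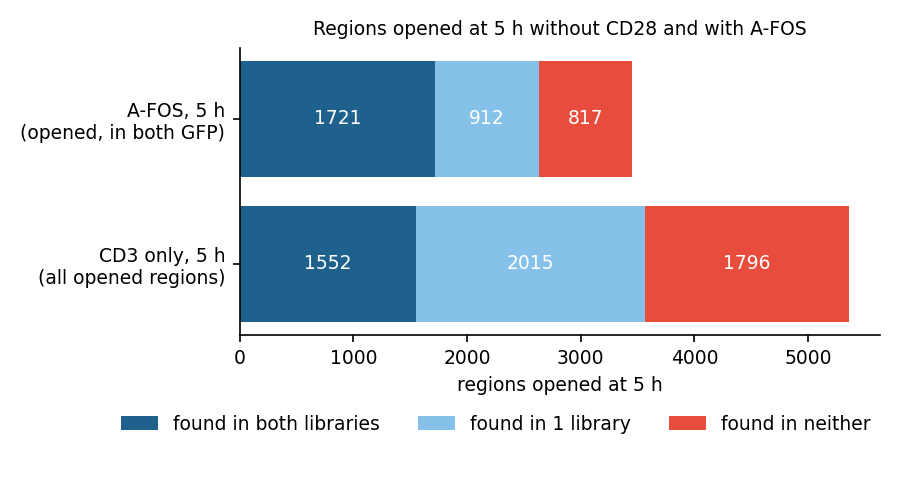
The bars give the number of regions opened at 5 h that had a peak in both, in 1 or in neither library of the CD3-only group (all 5363 opened regions) and of the A-FOS group (the 3450 also found in both GFP libraries). With anti-CD3 alone 1796 regions had a peak in neither library, and with A-FOS 817.

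The IL2 gene, which codes for the growth factor whose production depends on CD28, had a CD28-dependent intergenic region on chromosome 4 from 123370839 to 123373385. This region had a peak in 0 of 3 naive, 3 of 3 costimulated 5 h, 3 of 3 costimulated 24 h, 1 of 2 costimulated 60 h, 1 of 2 GFP, 1 of 2 A-FOS and 0 of 6 CD3-only libraries, where the naive and 5 h groups were set by its choice. Over all times IL2 had 4.88 ± 1.46 regions per library with costimulation (SD, n = 8) and 0.833 ± 0.408 with anti-CD3 alone (n = 6). IL21 had 11.2 ± 4.5 and 2.33 ± 0.82, and IFNG, the main effector cytokine of TH1 cells, had 10.8 ± 3.1 and 3.17 ± 2.14. STAT4, which carries IL-12 signals, had 14.1 ± 3.8 and 3.50 ± 0.55, and its upstream region on chromosome 2 from 192033951 to 192034597 had a peak in 3 of 3 costimulated 5 h, 1 of 2 costimulated 60 h and 0 of 6 CD3-only libraries. The 5 h values of this region, with and without CD28, were set by its choice as well. MYC had 2 CD28-dependent regions, and 5.12 ± 1.64 against 1.83 ± 1.17 regions per library. CD247 had 1 CD28-dependent region among 6 opened ones, CD3E had 0 of 2, and CD69 and CCR7 had 0 of 1 each, numbers too small to set genes apart. CCR7 had 6.12 ± 3.56 regions per library with costimulation and 6.67 ± 5.75 without.

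Gene by gene, no gene passed the stratified exact two-sided permutation test between 8 costimulated and 6 CD3-only libraries over all 16877 genes tested, with a smallest adjusted p of 0.108, while 2807 were at unadjusted p under 0.05. Adjusted over the list alone, 7 of 17 tested cytokine genes rose, by 9.61 regions per library for IL21, 7.56 for IFNG, 4.89 for TNFSF11, 4.0 for IL2, 2.22 for IL17A, 2.17 for CCL20 and 1.61 for LIF. Also adjusted over the list alone, 6 of 20 T helper genes rose, led by STAT4 by 10.8, AHR by 6.83 and PRDM1 by 6.67 regions, and 5 of 22 naive and quiescence genes, among them FOXP1 by 26.6, IL7R by 7.06, S1PR1 by 4.22 and FOXO1 by 3.67. The same adjustment over the list alone called 4 of 22 activation receptors, with CD44 up by 7.61 and CD274 by 1.72 regions, 3 of 20 NFAT, NF-kB and EGR genes, with NFKB1 up by 11.2 and NFKBIA by 3.61, 3 of 20 TCR signalling genes, with PTPRC up by 12.6 regions, and 3 of 16 anergy regulators, with IKZF1 up by 11 and CBLB by 10.2. It also called 2 AP-1 family genes, ATF3 and BACH1, 2 cell cycle genes, CDK6 and CDKN1B, and 2 B cell markers, EBF1 and CR2, by 8.33 and 2.33 regions. Regions per gene were not scaled for the 1.70-fold larger number of peaks, and as a share of a library's regions the CD28 difference was −0.0274 points for AP-1 family genes, −0.0240 for cell cycle genes and −0.0136 for TCR signalling genes (exact permutation, adjusted p = 0.360, 0.460 and 0.764). None of the 15 lists passed the test of CD28 dependence among opened regions. TCR signalling genes came nearest, with 5 of 40 opened regions CD28-dependent (12.5%) against 33.6% elsewhere (Fisher exact test, adjusted p = 0.0568), and cytokine genes had 7 of 16 (43.8%, adjusted p = 1). The TCR signalling list passed without naive replicate 2 or 3 or costimulated 5 h replicate 2, with adjusted p = 0.0289, 0.0271 and 0.0116 by the Fisher exact test.

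With anti-CD3 alone libraries had 24074 ± 8434 peaks (SD, n = 6), and over the 3 times costimulated libraries had 1.70 times as many, a log2 difference of 0.77 (stratified exact two-sided permutation test, p = 0.0133, 600 arrangements). By time the ratio was 1.48 at 5 h, 1.51 at 24 h and 2.21 at 60 h, and CD3-only libraries had 1.38 times the naive number (exact permutation test, p = 0.202). Between same-numbered libraries it was 1.07 and 1.59 at 5 h, 1.40 and 1.27 at 24 h, and 2.19 and 2.23 at 60 h. No label says that these numbers mark pairs. With peaks of at least 20 times the background the CD28 test gave p = 0.107, and without CD3-only 5 h replicate 2 it gave p = 0.05, both by exact permutation. The promoter share of peaks fell with CD28 from 51.4% ± 6.0 to 36.4% ± 6.5 (exact permutation test, adjusted p = 0.0208, n = 6 and n = 8). The intron share rose from 19.8% ± 1.8 to 27.1% ± 2.5 (exact permutation, adjusted p = 0.00833) and the intergenic share from 17.1% ± 1.5 to 24.5% ± 6.5 (adjusted p = 0.0306). Of the CD28-dependent regions, 94.3% lay away from promoters, against 88.5% of those kept in both CD3-only libraries (odds ratio 2.13, two-sided Fisher exact test across regions, p = 3.113e-09). The count of CD28-dependent regions can only stay or rise when a library is left out. It was 3283, 3061 or 2825 without replicate 1, 2 or 3 of the costimulated 5 h group. Without CD3-only 5 h replicate 1 it was 2922, and with the q limit 862. The promoter call ended without CD3-only 5 h replicate 2, at −12.7 points (exact permutation, adjusted p = 0.0521). The intergenic call ended without CD3-only 5 h replicate 1 or 2, at 7.64 and 6.42 points, or without CD3-only 24 h replicate 1 or 2, at 7.11 and 6.95 points. With lists of equal length the differences were −7.74 points for promoters, 4.72 for introns and 2.95 for intergenic peaks, against −15.1, 7.65 and 7.03 (exact permutation, adjusted p = 0.00278 each).

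In libraries that took no part in choosing them, the regions opened at 5 h were found more often with CD28. At 24 h 58.7% ± 16.0 of them had a peak in costimulated libraries (SD, n = 3) and 32.8% ± 5.9 in CD3-only libraries (n = 2), and at 60 h 63.8% ± 7.7 and 27.7% ± 3.8 (n = 2 each). The difference was 31.0 percentage points (stratified exact two-sided permutation test, p = 0.0333, 60 arrangements), and 14.8 points with lists of equal length (p = 0.0167). At 5 h, a costimulated library held out of the choice had 73.2% ± 0.4 of the regions chosen without it (n = 3), and the 2 CD3-only libraries had 35.6% to 47.5% of the same sets. Common regions, chosen in the same way, were found at 91.1% to 99.6% on average in each group. A naive library held out of the choice had 35.6%, 7.01% and 3.30% for replicates 1, 2 and 3, and without naive replicate 1 the difference was 27.8 points (exact permutation test, p = 0.05). Without replicate 1, 2 or 3 of the costimulated 24 h group it was 28.4, 35.6 and 29.0 points (p = 0.0556 each, exact permutation, the smallest that number of libraries allows). It missed the threshold with a −log10 q of at least 10 (exact permutation, p = 0.0667) and with the enrichment limit (p = 0.05), though the difference was no smaller there.

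**Figure D4:**
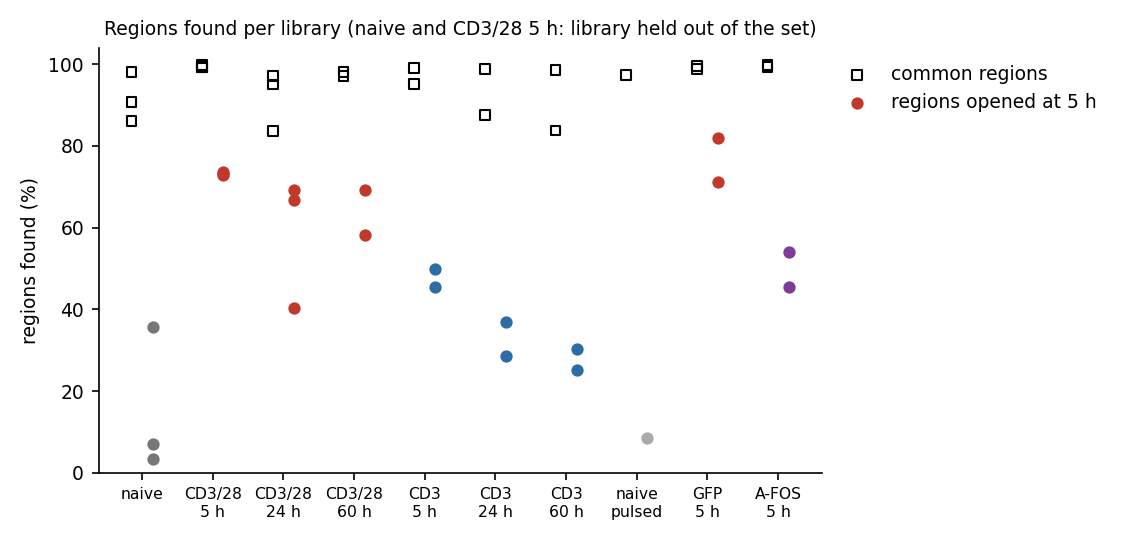
The percentage of regions opened at 5 h (filled points) and of common regions (open squares) that had a peak is plotted for each library. Costimulated libraries of 60 h average 63.8% of the opened regions and CD3-only libraries of 60 h 27.7%, while common regions average at least 91.1% in every group.

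Part of the opened regions had no peak with A-FOS, while common regions kept theirs. Of the 3450 regions opened at 5 h that had a peak in both GFP libraries, 817 (23.7%, 95% exact interval 22.3 to 25.1) had a peak in neither A-FOS library, 912 in 1 and 1721 in both. Of 8595 common regions found in both GFP libraries, 3 were lost. CAMK2D had the most A-FOS-sensitive regions, 7, and its number of regions per library was 19.0 ± 2.8 with GFP and 9.0 ± 2.8 with A-FOS (SD, n = 2 each). MAML2, a Notch coactivator, NEK7, PDE4B, PLCL2 and RUNX1, a regulator of T cell development, had 4 each, and ARID1B, CAMK4, CBLB, INPP4B, KLF12 and NFATC2 had 3 each. RUNX1 had 13.5 ± 0.7 regions with GFP and 7.0 ± 2.8 with A-FOS, and NFATC2 had 8 regions in each GFP library and 3.0 ± 2.8 with A-FOS. Genes named for A-FOS-sensitive regions, here and below, were chosen in these same libraries. Their lower counts with A-FOS therefore follow in part from the choice, and were not scaled for the larger number of peaks with GFP. ETS1, NRP1, IL2RA, CTLA4, AHR and PRDM1 had 0 A-FOS-sensitive regions, and NRP1 had 18 ± 4.2 and 16.5 ± 3.5 regions.

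Naive and quiescence genes had the highest A-FOS-sensitive share among lists with over 10 opened regions found in both GFP libraries, with 10 of 18 (55.6%) against 23.5% elsewhere (Fisher exact test, adjusted p = 0.0521 over 15 lists). They included 2 regions each at BACH2 and FOXP1, with 24.5 ± 0.7 regions per library at BACH2 with GFP and 16.5 ± 0.7 with A-FOS (SD, n = 2 each). NFAT, NF-kB and EGR genes had 6 of 13 (46.2%, Fisher exact test, adjusted p = 0.677), T helper genes 7 of 19 (36.8%, adjusted p = 0.677), TCR signalling genes 4 of 22 (18.2%, adjusted p = 1) and anergy regulators 5 of 20 (adjusted p = 1). Activation receptors had 4 of 15 (26.7%) and cytokine genes 2 of 7. Without GFP replicate 1 or without costimulated 5 h replicate 1 the naive and quiescence list passed, with adjusted p = 0.000147 and 0.0236 by the Fisher exact test. The region at CAMK2D on chromosome 4 from 114305440 to 114306348, between genes, had a peak in 3 of 3 costimulated 5 h libraries and both GFP libraries, and in 0 of 3 naive, 0 of 6 CD3-only and 0 of 2 A-FOS libraries. Its values in the naive, GFP, A-FOS and all 5 h libraries were set by its choice. Outside that choice it had a peak in 3 of 3 costimulated 24 h and 2 of 2 costimulated 60 h libraries. An intronic region of PDE4B on chromosome 1 from 66708998 to 66709965 was found in both GFP and 0 of 2 A-FOS libraries, as were an intronic region of BACH2 on chromosome 6 from 90735351 to 90735985 and a region upstream of NFATC1 on chromosome 18 from 77153059 to 77155401. Those GFP and A-FOS values were likewise set by the choice of the regions. The regions at BACH2 and NFATC1 had a peak in 6 and in 5 of the 6 CD3-only libraries.

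A-FOS-sensitive regions lay away from promoters more often than those kept in both A-FOS libraries, at 96.1% against 85.8% (odds ratio 4.05, two-sided Fisher exact test across regions, p = 7.227e-17). Introns held 54.8% of the sensitive and 39.6% of the kept regions. GFP libraries had 43607 ± 815 peaks and A-FOS libraries 33219 ± 4057 (SD, n = 2 each), a ratio of 1.32 (exact permutation test, p = 0.333, the smallest this design allows). The direction of that ratio turned with peaks limited to a −log10 q of at least 10, where A-FOS libraries had more by 0.03 on the log2 scale, and with peaks of at least 20 times the background, by 0.23. GFP libraries had 76.5% ± 7.6 of the regions opened at 5 h and A-FOS libraries 49.8% ± 6.0 (n = 2 each). The library electroporated without protein or activation had 8.45% of them. The share of lost regions, which leaving out an A-FOS library can only keep or raise, was 41.0% without A-FOS replicate 2. It was 43.5% with lists of equal length. Exon peaks at the 16 constitutive control genes numbered 15 and 13 in the GFP libraries, 14 and 14 in the A-FOS libraries and 10 in the electroporated naive library, against 1, 0 and 0 in the naive libraries, and the exon share of peaks was 3.31% ± 0.18 with GFP and 4.93% ± 0.32 with A-FOS.

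Loss with A-FOS and absence without CD28 went together across regions, though within bins of peak score this held only in part of the settings. Of the 3450 regions, 299 had a peak in neither A-FOS nor CD3-only 5 h libraries, among them the regions at CAMK2D and PDE4B given above and the upstream region of STAT4. A further 518 were lost with A-FOS alone, such as those at BACH2 and NFATC1, 586 were absent without CD28 alone and 2047 were neither. The odds ratio was 2.02 (two-sided Fisher exact test across regions, p = 1.447e-15), and 1.40 within 10 bins of the authors' peak score (p = 0.000232). Within the bins it was 1.01 with the q limit, 1.21 with the 50% cover limit, 1.61 with lists of equal length and 1.04 without CD3-only 5 h replicate 1, and none of these 4 values passed the Mantel-Haenszel test. Regions are not independent replicates. With regions lost from GFP libraries in place of A-FOS libraries, where no AP-1 inhibitor was given, the odds ratio within score bins was 1.74 (95% interval 1.43 to 2.11), against 2.17 (1.87 to 2.51) for A-FOS over the regions tested in the same way. With peaks of at least 20 times the background the odds ratio over all regions was 0.94 (Fisher exact test, p = 1).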

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

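The tests of sequencing depth in this part, of weak peaks in A-FOS beside GFP libraries, of copied RNA and of open gene bodies were chosen only after the result was seen, while the other tests were chosen before. Exon peaks at the constitutive control genes, such as ACTB and GAPDH, stood out in the library of electroporated naive cells, which enters no comparison. It had 10 such peaks, against 1, 0 and 0 in the 3 naive libraries. Among activated libraries, costimulated 5 h replicate 1 had 15 and CD3-only 5 h replicate 1 had 5, and their partners had 4, 4 and 1.

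More peaks were called in activated than in naive libraries and with CD28 than without. Depth as the whole cause was argued against: with the relative tag number taken out by its slope within groups, the log2 difference was 1.22 for activation (exact permutation test, p = 0.00606, n = 8 and n = 3) and 0.72 for CD28 (p = 0.0100), 101% and 94.5% of the unadjusted sizes. Library enrichment as the whole cause was argued against as well, with 1.16 for activation (exact permutation, p = 0.00606) and 0.61 for CD28 (p = 0.0150) after the median enrichment at common regions was also taken out. The slopes come from within-group differences of few libraries, so a part of either difference may still come from library quality. A hypothesis that stays open is that activation and CD28 themselves opened these regions, which read counts at a fixed set of regions, at equal read number per library, would test.

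Regions opened at 5 h, such as those at CAMK2D and PDE4B, were lost with A-FOS, and more often where the CD3-only libraries had no peak either. Weak peaks dropping out as the whole cause of the loss was argued against: within score bins the odds ratio of loss for opened against common regions was 246 (95% interval 123 to 493) for A-FOS and 10.9 (6.65 to 18) for GFP, so that the 169 (56.2 to 510) found among regions in both GFP libraries would not have been enough alone. The intervals here and below take regions as independent and hold no spread between libraries, with 2 libraries in each group. The values therefore speak for these libraries only. Few common regions were lost with A-FOS, 3 of the 8595 found in both GFP libraries, so the odds ratios rest on small counts. Fewer tags in the A-FOS libraries were argued against too, since after removal of the tag slope GFP libraries had 25.3 percentage points more of the opened regions, 94.9% of the unadjusted 26.7 points, with the lowest GFP library at 55.4% and the highest A-FOS library at 38.8%. For the link with CD28, weak peaks remain a candidate explanation: loss from GFP libraries, with no AP-1 inhibitor, went with absence from CD3-only libraries at an odds ratio of 1.74 (1.43 to 2.11), whose interval reaches that of A-FOS (2.17, 1.87 to 2.51), and within score bins the link was 1.01 with the q limit. That AP-1 acts at CD28-dependent regions may add to this, and the motif search that bears on it was not run.

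Regions found in both A-FOS libraries and in no other library lay in exons more often than those found in both GFP libraries alone, at 96 of 259 (37.1%, 95% exact interval 31.2 to 43.3) against 6 of 351 (1.71%, 0.630 to 3.68). They lay in 84 genes, among them FOS, on chromosome 14 from 75747447 to 75747684 and from 75748054 to 75748801, FOSB, TXNRD1 with 3, TNF, NR4A1, EGR3, HSPA5, HSP90AA1 and NCL. Ribosomal protein genes had the highest mean folds by the authors with A-FOS, 9.70 at RPL27A, 9.64 at RPS4X and 9.48 at RPS6. EEF2, PKM and ENO1 were among the 84 genes as well. The same genes had 1 such intron region, 1.04% of the exon number, which goes against open gene bodies with A-FOS at these genes only. They were chosen for an exon region, which lowers that share. The whole set held 76 intron regions (29.3%), so open gene bodies are not excluded. Copied RNA among the sequenced DNA may explain exon peaks at strongly transcribed genes, but the constitutive genes had 28 exon peaks in the A-FOS libraries together and 28 in the GFP libraries together, which leaves it undecided. A biological change at these exons was not tested, and costimulated 5 h replicate 1 with CD3-only 5 h replicate 1 had 139 exon regions among the 667 found in that pair alone, the most of any other pair of libraries.

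Counts from many regions or genes were compared with other splits of the same libraries. For regions opened at 5 h and at 24 h, the 10 splits of 6 libraries are too few for a share under 0.05. The real split was the 1 with the most, with 5363 regions against at most 508 in the others at 5 h and 4074 against at most 1179 at 24 h. For regions past the adjusted Fisher test, all 100 splits drawn gave 0, as did the real one. The smallest p this test can reach is 0.00606, and in simulated data it called 0 with 200 planted regions. That count could therefore not tell a change at few regions from chance, and chance is not excluded by it. For regions at unadjusted p under 0.05, 1 of 100 splits, the real one, gave 2947 and the others at most 1318. For genes at unadjusted p under 0.05, 2 of 100 splits gave at least the real number in each comparison, a share under 0.05. The real numbers were 2264 against at most 2509 in another split for activation and 2807 against at most 3755 for CD28. Regions per gene were not scaled for the number of peaks, and 1 other split gave more. This share therefore does not exclude chance for the genes.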

How the results depend on the processing

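The limit to peaks of at least 20 times the background and the share of regions at a list's genes were chosen after the data were seen. The cause was not tested for any change given here, except that stricter limits and equal lists leave fewer peaks by construction. Leaving out a library can, also by construction, only keep or raise the counts of opened and of CD28-dependent regions.

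With a −log10 q of at least 10, the activation difference in peak number was 0.83 on the log2 scale (exact permutation p = 0.0970), A-FOS libraries had 0.033 more than GFP libraries, and 2219, 1017 and 2996 regions opened at 5, 24 and 60 h. CD28-dependent regions numbered 862, the A-FOS-sensitive share was 27.6% and the recovery difference 33.2 points (exact permutation p = 0.0667). Class differences that then passed were 2.47 points for upstream and 8.74 for intergenic peaks with activation, and 1.75 for upstream and 0.75 for exon peaks with CD28 (exact permutation, adjusted p = 0.00417 and 0.0250), where the exon direction had turned. With an enrichment of at least 20, the differences were 1.03 for activation (exact permutation p = 0.127), 0.59 for CD28 (p = 0.107) and 0.23 for A-FOS over GFP, 774 and 1636 regions opened at 5 and 24 h, 44 were CD28-dependent, the A-FOS-sensitive share was 34.6%, the recovery difference 31.1 points (p = 0.05) and the odds ratio of A-FOS and CD28 loss 0.94, while upstream and intergenic differences of 2.55 and 8.84 points passed. With lists of equal length, 1025, 1830 and 2386 regions opened and 315, 1214 and 1208 closed, 176 were CD28-dependent, the A-FOS-sensitive share was 43.5% and the recovery difference 14.8 points (exact permutation p = 0.0167). Class differences were then −15.0 points for promoters and 9.22 for introns, upstream and intergenic differences of 0.54 and 5.22 passed, and with CD28 they were −7.74, 4.72 and 2.95 points for promoters, introns and intergenic peaks. The odds ratio of A-FOS and CD28 loss within score bins was 1.01 with the q limit, 1.21 with 50% cover, 1.61 with equal lists and 1.04 without CD3-only 5 h replicate 1. With peaks covering 50% of a region, 1500 regions opened at 24 h and the A-FOS-sensitive share was 16.3%. By share of a library's regions, 2 lists passed for activation, cytokines and T helper genes (adjusted p = 0.0455 each, exact permutation). The exon share with CD28, lower by 0.31 points, was higher by 0.75, 0.64 and 0.47 points with the q limit, the enrichment limit and without CD3-only 5 h replicate 1, and the difference was −1.09 points without CD3-only 5 h replicate 2.

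Leaving out each library in turn gave log2 differences of 1.05 to 1.52 for activation, 0.61 to 0.92 for CD28 (p = 0.05 without CD3-only 5 h replicate 2, exact permutation) and −0.52 to −0.27 for A-FOS. Opened regions ran from 5546 to 8325 at 5 h, the highest without naive replicate 1, from 4125 to 8413 at 24 h, the highest without costimulated 24 h replicate 2, and from 11728 to 26836 at 60 h, where leaving out replicate 1 gave 17491 and replicate 2 the highest. Recovery differences ran from 27.8 to 35.6 points, CD28-dependent regions from 1822 to 3283, A-FOS-sensitive shares from 17.5% to 41.0% and odds ratios from 1.69 to 2.49. Class differences ran from −32.2 to −22.3 points for promoters, 1.15 to 2.64 for upstream, 0.23 to 0.79 for exons, 11.5 to 16.3 for introns and 8.80 to 12.4 for intergenic peaks. Regions past the Fisher test stayed at 0, and 0 to 2 gene lists passed, among them TCR signalling without naive replicate 1 (adjusted p = 0.0210).

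Whether replicate numbers pair the samples was not settled. Same-numbered naive and 5 h libraries had correlations of 0.10, −0.08 and 0.15 in their deviations from the group means. Same-numbered costimulated and CD3-only libraries of 5 h had 0.18 and −0.10. With a replicate block the activation difference was 1.2 (exact permutation p = 0.0208), that of CD28 0.65 (p = 0.0312) and the recovery difference 29.0 points (p = 0.125, the smallest that 4 pairs allow). The 5363 regions opened at 5 h cannot change with the block, since it asks the same of each library. Of the main results, 172 values stayed on their side of the threshold or within range, 38 moved, 15 lost and 9 gained a call and 3 turned. Of the 83 named genes with a region opened at 5 h, 54 had one with the q limit, 63 with the cover limit, 39 with equal lists and 31 with the enrichment limit. The 4 alternatives of the AP-1 motif search were not run. Depth limits the lists: the weakest peak called lay at 5.55 to 16.7 times the background.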

Other observations

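The comparison of list shares in this part was chosen after the data were seen. Cytokine genes took a larger share of all regions in the 8 costimulated libraries of the time course than in naive ones, and T helper lineage genes did too. Cytokine genes held 0.109% ± 0.023 of the regions of naive libraries and 0.194% ± 0.022 at 5 h (SD, n = 3 each), and over the 8 costimulated libraries the share rose by 0.0929 percentage points (exact two-sided permutation test, adjusted p = 0.0455 over 15 lists). With anti-CD3 alone at 5 h the share was 0.137% ± 0.005 (n = 2), and the CD28 difference of 0.0746 points had an adjusted p of 0.05. T helper lineage genes held 0.225% ± 0.038 in naive libraries and 0.362% ± 0.067 at 5 h, and the share rose by 0.115 points over these 8 costimulated libraries (adjusted p = 0.0455, exact permutation). The rise was smaller in the GFP libraries, also costimulated for 5 h. There cytokine genes held 0.130% ± 0.034 and T helper genes 0.284% ± 0.019 (n = 2), against 0.100% and 0.193% in the electroporated naive library. TCR signalling genes held 0.266% ± 0.058 in naive libraries, 0.476% ± 0.093 at 5 h and 0.478% ± 0.006 with anti-CD3 alone at 5 h (adjusted p = 0.0909 for activation and 0.764 for CD28, exact permutation, n = 11 and n = 14 libraries). Constitutive control genes held 0.152% ± 0.021 in naive libraries and 0.113% ± 0.033 at 5 h (adjusted p = 0.0606, exact permutation).

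NR4A2, an early nuclear receptor gene, had region numbers that differed most between replicates among the named genes, with 2.33 ± 0.58 in naive libraries, 42.0 ± 57.2 at 5 h (SD, n = 3 each) and 59.0 ± 22.6 with GFP and 13.0 ± 1.4 with A-FOS (n = 2 each). BACH2 had 54.0 ± 34.2 regions at 5 h with costimulation and 38.5 ± 24.7 with anti-CD3 alone. The effect of CD28 on peak number was larger at 60 h than at 5 and 24 h by 0.57 on the log2 scale, which did not pass an exact two-sided permutation test (p = 0.295, 420 arrangements). Over all regions, not only opened ones, 2763 had a peak in both GFP and neither A-FOS library and 1098 the reverse, while 16787 had one in all 4.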
